A study of Drosophila melanogaster with 189 samples.

How the data were processed

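The series holds 189 RNA-seq libraries of adult Drosophila melanogaster. Of these, 157 were made from flies whose gonads had been removed by hand, in 48 groups of sex, hours at 29 °C and line. The other 32 were made from ovaries or testes of 4 lines at 0 h, in 8 groups of 4. Per the labels' protocols, flies were reared at 20 °C, collected 0 to 4 h after eclosion and moved to 29 °C, which lifts the block that Gal80ts places on a ubiquitous tubP-Gal4 driver. Each library came from a pool of 3 flies, so the spread reported here is between pools. Where a mean covers both sexes or both sham lines, its SD also holds the differences between them. The labels do not say that pools of the same replicate number were handled together, and the replicate number was used as a block only as an alternative.

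The submitters' processing notes state that reads of 50 bases were called with CASAVA 1.8.2, aligned to BDGP6 with STAR 2.4.2a and assigned to genes of the FlyBase r6.04 annotation with HTSeq 0.6.1p1, with SAMtools 0.1.19 for file handling. The deposited values are counts of uniquely mapped, strand-specific reads per gene, as the authors made them. The deposited table has 17468 fly genes, 96 spike-in entries and 5 summary entries. All 189 per-library files matched the merged table in every fly gene. They differed from it in spike-in or no-feature values for 138 libraries, in 7 spike-in entries, and the merged table was used here. Gene symbols and positions came from the deposited annotation. Whether duplicate reads were removed is not given in the sources used here.

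Fly gene counts per library ran from 2741962 to 8167264 in bodies without gonads (median 5011697), from 3646254 to 8946925 in ovaries and from 3906690 to 6931918 in testes. Bodies had 10828 to 14296 genes with a count. Their 10 most abundant genes held 6.86% to 20.0% of the fly gene counts. Reads outside genes were 4.40% to 9.48% of uniquely mapped reads in bodies, 3.06% to 5.75% in ovaries and 6.39% to 10.2% in testes. Spike-in reads were 0.0840% to 0.643% of the uniquely mapped reads of bodies. Per the labels, the spike-in pools differed between the sham lines and the other lines, so spike-ins were not used to scale libraries. Changes in the total RNA per fly were therefore not analysed here.

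Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr at its default settings, which left 12468 genes in bodies and 11505 in gonads. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions and 1 mean per group was fitted to the 157 body libraries or to the 32 gonad libraries. Each contrast of group means was tested by the quasi-likelihood F test, two-sided, with p adjusted by Benjamini and Hochberg over the genes of that contrast and called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE). Levels are CPM, the fly gene counts of a library scaled to the same sum,, as mean ± SD over the pools named.

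For each of 6 lines the main contrast was the line against the mean of the 2 sham lines at 48 h, averaged over the sexes. The same contrast was made at 24 h and at 0 h. A further contrast subtracted the 0 h difference from the 48 h difference, and another compared the 48 h difference between males and females. The 2 dominant negative Cdk9 lines were compared with each other at 48 h. Shams were compared by sex and by line at 48 h, and from 0 h to 48 h. Each RNAi line was compared with lacZ within ovaries and within testes. The labels' protocols put the samples of the temperature shift on a first plate. Whether the 0 h libraries shared it is not given in the sources used here, so time may be mixed with library batch. The beyond-0 h contrast rests on shams and lines having shared each batch. Flies at 48 h were also older than those at 0 h, and a line difference that appears with age is not subtracted by that contrast.

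Genes named in the text followed a rule fixed in advance. At 48 h they passed the test at 48 h and beyond 0 h with the same sign, had that sign in each sex, and reached 5 CPM in the line or the shams. The 10 largest increases and 10 largest decreases were taken. In other contrasts the 5 largest in each direction with 5 CPM in a group were taken. Targets and members of the gene lists were named as well, with up to 4 examples per list and line.

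The 29 lists of genes covered transcription elongation, heat shock proteins, antimicrobial peptides, Turandot genes, detoxification, apoptosis and DNA damage, JNK and injury, immediate early factors, midgut digestive enzymes, fat body, insulin signalling, muscle, cytoplasmic and mitochondrial ribosomal proteins, the proteasome, Cpr cuticle proteins, chorion, female germline, testis, accessory gland, yolk proteins, dosage compensation with sex determination, photoreceptors, neurons, hemocytes, the clock, ecdysone with juvenile hormone, Hox genes and line marker genes. They were tested at 48 h with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists of a line. The test was repeated with the correlation between genes estimated per list. Beside each call the text gives how many members passed over all genes and how many passed with p adjusted over the list alone.

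The X to autosome value of a library was the mean log2 of CPM plus 1 over 1758 X genes minus that over 9262 genes of 2L, 2R, 3L and 3R, all with a mean of at least 1 CPM. Lines were compared with shams by a two-sided exact permutation test of 3 against 6 pools in each sex, over 84 assignments, with 0.0119 as the smallest possible p and adjustment over 12 tests. This value and the figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

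Gonad RNA left in bodies was measured as the level of 29 ovary or 17 testis marker genes relative to the lacZ organ, where the markers reached at least 100 CPM. Libraries at 2% or more were treated as holding gonad RNA.

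The groups, the tests, the naming rule, the lists and the following alternatives were set before the data were examined: w or lacZ alone as control, only the libraries of a contrast fitted, a mean CPM of at least 5, no filter, size factors of DESeq2 (RLE), the Wald test of DESeq2 1.42.0, a replicate block, each replicate number left out of every group in turn, each organ fitted alone, estimated correlations, and for X to autosome values the median, a minimum of 10 CPM, a pseudocount of 0.1, 24 h libraries and permutations within replicate numbers. Chosen after seeing the data were leaving out the libraries that hold gonad RNA and leaving out 4051 genes at least 5-fold enriched in a gonad. Whole-group splits of the compared libraries were drawn 60 times per contrast, or all 35 in gonads, and fitted to the compared libraries alone with both shams pooled, so their values differ from those of the full fit.

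The tests were checked on simulated counts with 200 changed genes. All genes had the same fixed dispersion, the changed genes were taken above a minimum level, and only the 48 h bodies or the gonads were simulated. The shares below hold for these settings and may differ in the data. For the lilli comparison at 48 h, edgeR recovered 53.7% of genes changed 1.5-fold, 98.5% at 2-fold and 100% at 4-fold, with 6.67% false calls, against 11.9% with DESeq2. For the lilli ovary the shares were 25.4%, 82.1% and 100%, with 2.82% false calls, against 7.89% with DESeq2. The list test called the 1 raised list and 0 others among its 174 tests. Its genes were simulated independently of each other, so this does not measure false calls for lists whose members correlate.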

Results

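The libraries measured polyA+ RNA of flies without gonads from 8 lines after 0, 24 or 48 h at 29 °C, and of ovaries and testes at 0 h. In 3 lines a ubiquitous Gal4 driver expressed RNAi against gpp, the fly homolog of the histone methyltransferase Dot1L, or against lilli or Su(Tpl), parts of the super elongation complex. In 2 lines it expressed a dominant negative form of Cdk9, the kinase of P-TEFb, from 1 insertion (DNifm) or from 2 (DNifmDNcff). Another line expressed the germline gene stil, and the shams were w and lacZ. Bodies numbered 63 libraries at 0 h, 46 at 24 h and 48 at 48 h, with 3 pools per group at 48 h. Of the 56 groups, 23 had 4 pools, 31 had 3 and 2 had 2 (DNifmDNcff and stil females at 24 h). Fly gene counts per body library had a median of 5011697. Positions are on BDGP6.

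The first question was whether each line changed its target. Su(Tpl) (FBgn0014037, 3L 19889120 to 19909410) was at 148 ± 13.0 CPM in its RNAi line at 48 h (n = 6) and 295 ± 14.9 in shams (n = 12), a log2 fold change of -1.04 (SE 0.04, adjusted p = 4.6e-44). lilli (FBgn0041111, 2L 2885929 to 2954406) was at 64.9 ± 7.96 against 92.3 ± 8.28 CPM, a change of -0.65 (SE 0.07, adjusted p = 4.0e-14). gpp (FBgn0264495, 3R 6406855 to 6449274) was at 74.8 ± 12.7 against 95.02 ± 13.3 CPM, and its change of -0.32 (SE 0.11) did not pass the test (adjusted p = 0.0989). It passed without replicate 3 of every group, with a change of -0.42 and an adjusted p of 0.00314. Cdk9 (FBgn0019949, 2R 22636063 to 22637727) rose to 411 ± 68.2 CPM in DNifm and 382 ± 147 in DNifmDNcff from 14.6 ± 2.36 in shams, changes of 4.87 (SE 0.11) and 4.78. These counts hold reads of the transgene and of the endogenous gene together. stil (FBgn0003527, 2R 12570367 to 12571883) rose to 81.1 ± 17.9 CPM from 0.484 ± 0.704, a change of 7.23 (SE 0.62, adjusted p = 1.9e-18).

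Most targets had moved at 24 h, and some before the shift. At 24 h the changes were -1.03 for Su(Tpl), -0.60 for lilli, 4.82 and 4.92 for Cdk9, and -0.22 for gpp (adjusted p = 0.191). At 0 h Su(Tpl) was already lower (-0.43, adjusted p = 1.3e-19; 243 ± 12.9 against 330 ± 27.3 CPM), as was lilli (-0.18, adjusted p = 0.0406), while gpp did not pass (0.01, adjusted p = 0.980). That value averages gpp females at 124 ± 35.8 against 103 ± 12.8 CPM, 2 of whose 4 pools held ovary RNA, and males at 94.8 ± 2.06 against 108 ± 8.33. Cdk9 stood at 135 ± 13.3 and 139 ± 42.6 CPM against 16.1 ± 2.54 at 0 h (n = 8 and 15), and rose further by 1.76 and 1.68 by 48 h. stil stood at 11.2 ± 4.16 CPM at 0 h against 0.151 ± 0.395. In gonads at 0 h (n = 4 and 4) the RNAi targets were not lower. Ovary values were 388 ± 16.3 against 377 ± 8.42 CPM for gpp, 193 ± 2.81 against 178 ± 7.47 for lilli and 546 ± 15.5 against 539 ± 15.4 for Su(Tpl). The fitted change of Su(Tpl) was 0.22 (adjusted p = 0.0245), where the median change over all genes was 0.17. Testis values were 645 ± 8.77 against 623 ± 21.1, 259 ± 13.7 against 259 ± 10.8 and 515 ± 48.1 against 496 ± 10.02.

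**Figure D1:**
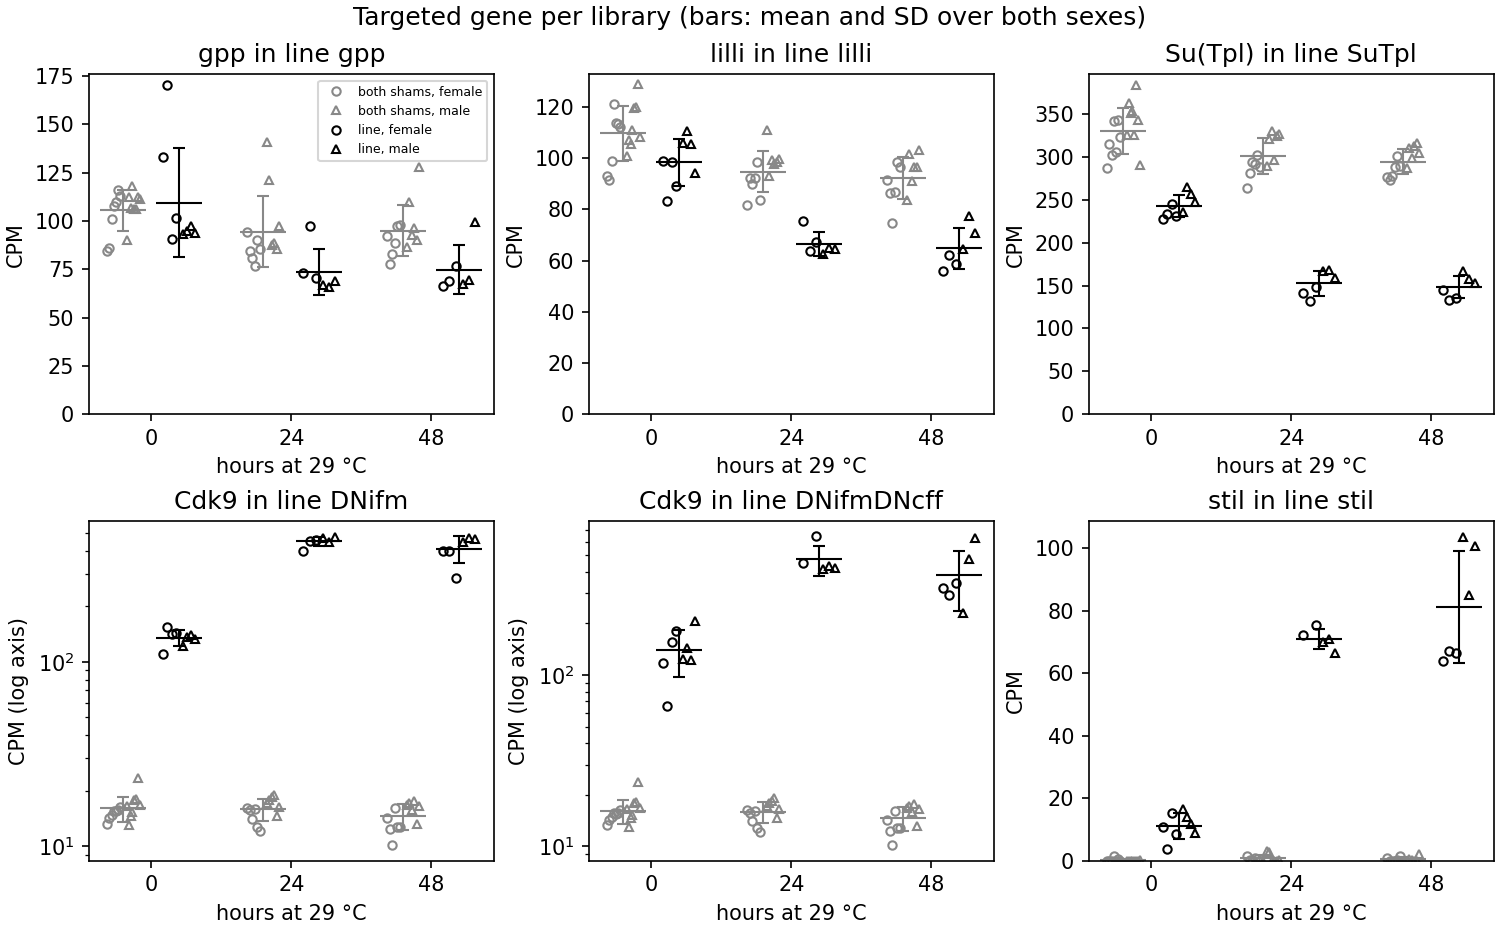
Level of each line's target gene (CPM) in each body library against hours at 29 °C, with females as circles, males as triangles, the line in black and both shams in grey, and bars for the mean and SD over both sexes (log axes for Cdk9). Su(Tpl) fell from 295 CPM in shams to 148 in its line at 48 h, and Cdk9 rose from 14.6 to 411 and 382.

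Sham bodies of the sexes differed in 5217 of 12468 genes at 48 h, 3212 of them higher in males. Acp63F (3L 3815839 to 3816354), a seminal protein, was at 187 ± 26.2 CPM in males and 0.0989 ± 0.162 in females (n = 6 each). The dosage compensation RNAs roX2 and roX1 were higher in males by 10.18 and 6.99, and the yolk protein genes Yp1, Yp2 and Yp3 had changes of -9.15, -9.08 and -8.82. CG31681 (2L 2285925 to 2286873) had -10.05. All 23 accessory gland genes were higher in males, over all genes and over the list alone, as were 20 of 26 testis genes. Line contrasts average the sexes, so genes near 0 in females, such as Acp63F, take part of their change from those low counts. This limit applies to the accessory gland calls of every line below. Of 17 chorion genes 10 were lower in males (11 over the list alone), and of 86 cytoplasmic ribosomal protein genes 82 were lower and 2 higher. Of 38 midgut digestive enzymes 27 were lower and 4 higher (5 over the list alone), and all 10 hemocyte genes were lower. Of 13 neuronal genes 12 were higher. The count fell to 2861 without replicate 2 of every group and to 3059 without replicate 3.

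RNA of gonads was measured in some bodies, and the sex and line contrasts of chorion, germline and testis genes moved with it. The median female body had 0.319% of the ovary marker level and the median male body 0.122% of the testis marker level. Of all bodies, 26 had 2% or more, in 21 groups. Replicate 3 of DNifm females at 48 h had 46.3% of the ovary level, replicates 2 and 1 of gpp females at 0 h had 29.0% and 17.7%, and replicate 1 of DNifm females at 24 h had 10.6%. The highest testis levels were 8.84% in replicate 1 of lilli males at 0 h and 7.78% in replicate 2 of SuTpl males at 0 h. Ovary markers were also found in 2 male bodies, replicate 1 of stil males at 0 h (4.50%) and replicate 1 of lacZ males at 24 h (2.76%).

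**Figure D2:**
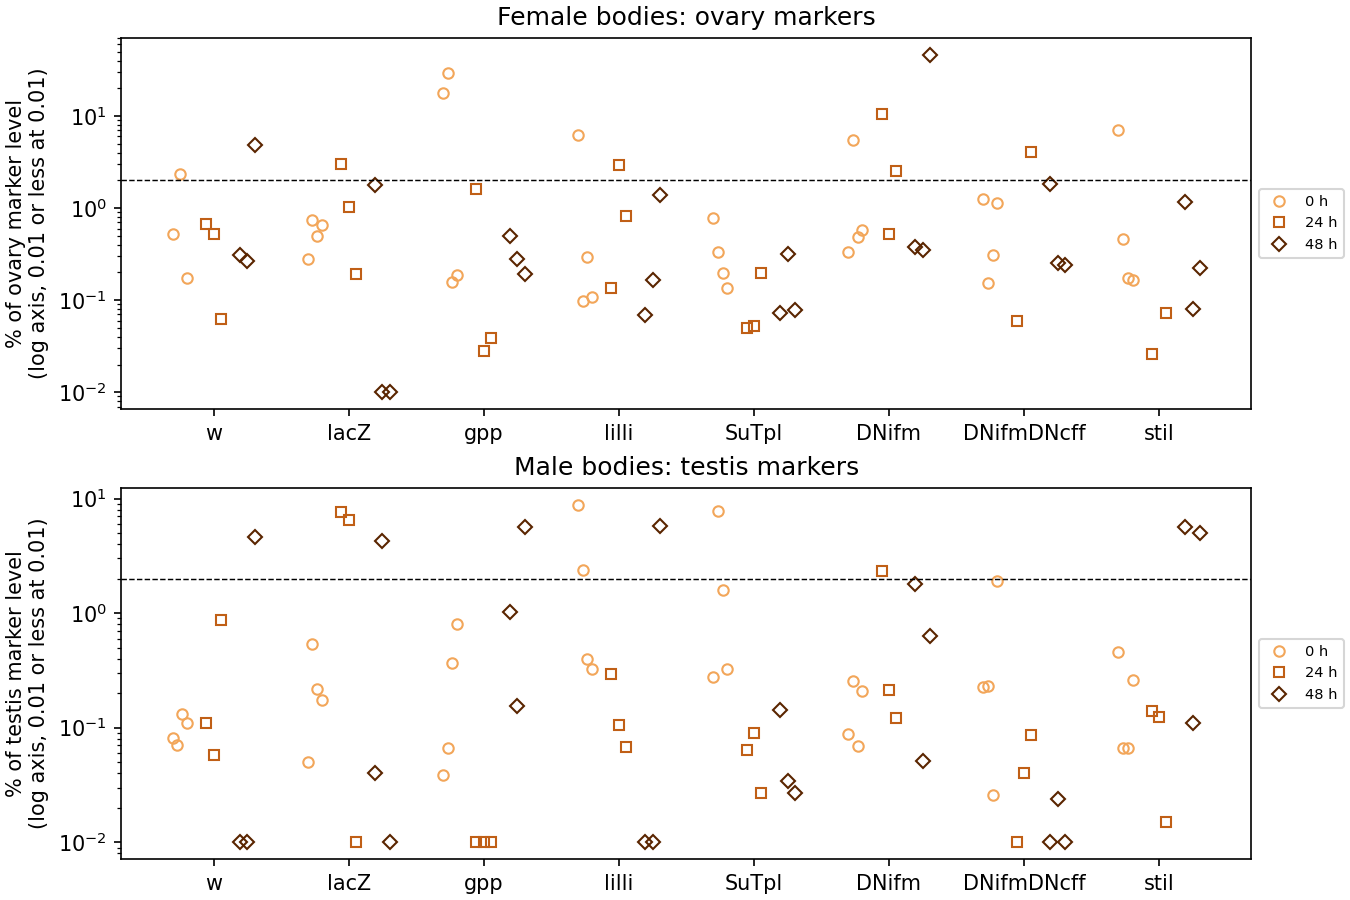
Gonad marker level in each body library as a percent of the level in lacZ ovaries (females) or testes (males), on a log axis with values of 0.01 or less drawn at 0.01, by line and hours. The dashed line is at 2%, and the highest female value is 46.3% in DNifm at 48 h.

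Sham lines differed from each other in 191 genes at 48 h, 109 of them higher in lacZ. The lysozyme genes LysS (3L 1227747 to 1228238) and LysD (3L 1210717 to 1211196) were at 2.19 ± 1.17 and 39.9 ± 13.6 CPM in lacZ and 134 ± 96.0 and 1588 ± 888 in w (n = 6 each), changes of -5.79 and -5.15. LysC, LysB and LysE had -5.50, -5.24 and -3.62; lysozyme genes are close copies that may share reads. The cytochrome P450 gene Cyp4p2 (2R 9237512 to 9239831) was 5.65 higher in lacZ. The count was 88 without replicate 1 and 112 without replicate 2. From 0 h to 48 h shams changed 4807 genes, 2621 upward. Temperature, age after eclosion and possibly library batch change together here, so none of them can be told apart. The larval storage protein gene Lsp1beta (2L 898500 to 901316) rose to 339 ± 217 CPM from 2.17 ± 1.23 (n = 12 and 15) and the cuticle gene Cpr72Ec (3L 16365894 to 16367340) to 98.5 ± 19.7 from 2.77 ± 1.33. Dro, an antimicrobial peptide gene, changed by -4.07 and dec-1 by -3.55. Of 38 midgut enzymes 23 rose and 1 fell, and of 72 mitochondrial ribosomal protein genes 44 rose and 6 fell (47 and 6 over the list alone). Of 33 Cpr genes 12 fell and 4 rose, of 16 apoptosis and DNA damage genes 8 fell and 3 rose, and in the clock list per fell by 0.78 while tim rose by 0.91.

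The gpp RNAi line differed from shams in 374 genes at 48 h, 211 of them higher, and 84 by 2-fold or more. CG5830 (3L 15992669 to 16004736) rose to 203 ± 16.6 CPM from 135 ± 14.3 (0.61, SE 0.06, adjusted p = 5.0e-14) and CG10924 (2R 18527430 to 18535749) by 0.92 (SE 0.11). The apoptosis gene hid (3L 18167745 to 18185641) rose by 0.53 (20.6 ± 4.16 against 14.6 ± 3.07 CPM). The P450 gene Cyp6a14 (2R 8564187 to 8567202) was at 0.825 ± 0.384 against 5.02 ± 5.45 CPM (-2.29, SE 0.36), CG4734 (2R 13297202 to 13298467) had -1.12 and the lysosomal mannosidase gene LManVI (2L 8777661 to 8781252) -1.11, with LManV at -0.76. The glycogen branching enzyme gene AGBE had -0.63 and the actin gene Act5C (X 5900861 to 5905399) -0.52, at 1093 ± 200 against 1640 ± 539 CPM. Sirup, CG4716, gol, Cyp28a5, laza, comm3 and CG42554 were the other named increases, and fra, SsRbeta, Tapdelta and LanA the other decreases. The count was 150 without replicate 1 and 155 without replicate 3. At an unadjusted p under 0.05 there were 1591 genes.

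In gpp bodies 9 of 25 detoxification genes fell, 12 over the list alone (camera adjusted p = 7.2e-11, and 0.468 with an estimated correlation), among them Cyp6a8 (-1.33, SE 0.25), Cyp6a23 (-0.88) and Cyp6a20 (-0.69). Heat shock genes were called up (adjusted p = 0.0125, estimated 0.707) through Hsp70Bb (4.79, SE 0.44), with 1 of 14 rising and 3 over the list alone; Hsp70 copies may share reads. Cpr genes were called up (0.0038, estimated 0.707) with Cpr76Bd (0.61) and Cpr51A (0.57), 2 of 33 and 4 over the list alone. Fat body genes were called up (0.0428, estimated 0.779) with Desat1 and Lsd-2 (0.30), 2 of 20 either way. JNK genes were called down (0.0428, estimated 0.707) with Gadd45 (-0.58) falling and kay (0.30) rising among 9, and 2 falling over the list alone. The proteasome (down, 1.4e-08, estimated 0.707), mitochondrial ribosomal proteins (down, 0.0162, estimated 0.743) and muscle (up, 0.0025, estimated 0.896) were called on small shifts. In these 3 lists edgeR called 0 members, with 8 of 31, 13 of 72 and 6 of 25 at an unadjusted p under 0.05, and DESeq2 also called 0. Over the list alone 2 proteasome genes passed. Beyond the 0 h difference the detoxification (adjusted p = 0.9199), JNK (0.8294), Cpr (0.8294) and fat body (0.943) lists were not called, so their change was not shown to follow the shift. Heat shock (0.0293), muscle (5.3e-05), proteasome (1.2e-12) and mitochondrial ribosomal (2.0e-09) lists kept their direction there. In this and every other line the calls beyond 0 h were made at the preset correlation only, and no list called at 48 h stayed called at an estimated correlation. The gpp contrast beyond 0 h holds the 2 female pools with ovary RNA at 0 h. Without such bodies it called heat shock (0.0127), proteasome (0.0127) and mitochondrial ribosomal genes (1.7e-05) but not muscle (0.9497). Photoreceptors (up, 5.0e-13), neurons (up, 8.9e-06) and cytoplasmic ribosomal proteins (down, 2.2e-05) were called beyond 0 h and not at 48 h, also without those bodies (2.7e-11, 0.0121 and 1.7e-04). Elongation (down) and clock genes (up), at 0.0164 each, were not called without them (0.489 and 0.141). At 48 h without bodies that hold gonad RNA muscle (0.0544), JNK and Cpr genes (0.0554 each) were not called.

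The lilli RNAi line differed from shams in 1534 genes at 48 h, 717 higher and 817 lower, 334 by 2-fold or more. It differed in 1055 genes before the shift, and 393 changed beyond the 0 h difference. CG7900 (3R 8094124 to 8105083) rose to 77.4 ± 2.12 CPM from 18.4 ± 2.39 (1.93, SE 0.08, adjusted p = 3.4e-42), CG8646 (2R 12655954 to 12659341) by 1.33 and CG18417 and PH4alphaPV by 1.28 each. The maltase gene Mal-A2 (2R 8453627 to 8455782) rose by 1.09 to 206 ± 24.4 from 88.7 ± 20.2 CPM. CG30033 (2R 11292531 to 11293591) was at 0.545 ± 0.255 against 8.64 ± 2.99 CPM, and CG8299 (2R 15940610 to 15941483) at 2.08 ± 0.501 against 30.7 ± 14.5 (-3.94). The serine protease genes Jon99Fii (3R 30487016 to 30487928) and Jon99Fi had changes of -2.75 (SE 0.23; 78.5 ± 43.9 against 466 ± 244 CPM) and -2.63, and LManVI had -2.68 (158 ± 17.4 against 954 ± 314 CPM). Uro (2L 7780085 to 7781415), the urate oxidase gene of the Malpighian tubules, had -2.66 and CG10513 -2.83. CG4020, CG31148, CG5361, CG9459 and CG6310 were the other named increases, and CG43680, CG7829 and CG32483 the other decreases. Without replicate 1 the count was 921, and 2687 genes had an unadjusted p under 0.05.

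Of 38 midgut digestive enzymes in the lilli line, 24 fell and 2 rose, 27 and 4 over the list alone, with a median of -1.27 (camera adjusted p = 4.4e-23, estimated 0.331); Jon66Ci had -2.91. Detoxification genes fell in 10 of 25 and rose in 2, 11 and 3 over the list alone (8.3e-05, estimated 0.705), with Cyp6a8 at -2.50 and Cyp6a20 at -1.19. Muscle genes fell in 11 of 25, 17 over the list alone (2.8e-07, estimated 0.773), with TpnC73F at -0.65 and Act57B at -0.63. The proteasome was called up (2.5e-05, estimated 0.773) with 5 of 31 higher, 6 over the list alone, Prosbeta6 and Rpt4 (0.21) among them. In the JNK list Gadd45 (-0.53), scaf (-0.43) and puc (-0.30) fell, 3 of 9 either way (0.0094, estimated 0.587). In the insulin list Thor (-1.02), ImpL2 (-0.86) and Ilp3 (-0.66) fell, 3 of 14 either way (0.0109, estimated 0.415). Accessory gland genes were called down (0.0169, estimated 0.881) on a median of -0.58, with 0 of 23 called by edgeR, 0 at an unadjusted p under 0.05 and 1 by DESeq2. Part of that median can come from low counts in females, as the contrast averages the sexes. Midgut (8.1e-22), muscle (5.4e-06) and proteasome (1.8e-04) lists were also called beyond the 0 h difference. Detoxification (0.982), JNK (0.521), insulin (0.101, and 0.0245 without bodies that hold gonad RNA) and accessory gland genes (0.0742, upward) were not. Beyond 0 h, but not at 48 h, fat body (0.0102), Cpr (0.00878) and testis genes (0.00182) were called down and mitochondrial ribosomal proteins up (0.0291), of which testis genes were not called without those bodies (0.239).

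The SuTpl line differed from shams in 797 genes at 48 h, 431 higher and 366 lower, 169 by 2-fold or more. It differed in 821 genes before the shift, and 99 changed beyond the 0 h difference, so the 797 may include differences present before the shift. Su(Tpl) itself was already lower at 0 h, so such differences need not be line background. The contrast beyond 0 h also had a larger SE (0.053 against 0.042 for Su(Tpl)), which lowers its count. CG4822 (2L 116970 to 121754) rose by 0.64 (SE 0.11; 95.02 ± 8.41 against 59.4 ± 9.17 CPM) and CG5830 by 0.63. The TNF ligand gene egr (2R 10078366 to 10084210) rose by 0.30 (38.6 ± 4.56 against 30.4 ± 4.03 CPM) and the autophagy gene Atg14 by 0.28, with Cyp6a13, CG33080, DAAM and GNBP2 also among the named increases. The metallothionein gene MtnB (3R 20503102 to 20503746) was at 3.44 ± 1.64 against 20.9 ± 13.8 CPM (-2.56, SE 0.31). CG30033 had -2.76, CG11912 (2L 318362 to 319259) -2.35, CG8299 -2.32, Porin2 -2.28, CG8620 -1.77 and LManIV and LManVI -1.62 each. Arc1 (2R 14357927 to 14360297), which encodes a capsid-like protein, was at 82.7 ± 8.92 against 276 ± 139 CPM (-1.67). Gnmt, the glycine methyltransferase gene, had -1.62, made of -3.17 in females and -0.07 in males. The count was 372, 412 and 495 without replicates 1, 2 and 3 in turn, and 2076 genes had an unadjusted p under 0.05.

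In the SuTpl line 17 of 38 midgut enzymes fell and 1 rose, 20 and 2 over the list alone (adjusted p = 8.1e-11, estimated 0.717), with Jon66Ci at -1.90, deltaTry at -1.63 and Jon99Fi at -1.54. Detoxification genes fell in 8 of 25 and rose in 1, 13 and 2 over the list alone (1.1e-07, estimated 0.638), with Cyp6a8 at -2.08 and Cyp6a20 at -1.07. Of 10 hemocyte genes PPO1 (0.65), vkg, Pxn (0.34) and Cg25C (0.30) rose, 4 either way (0.00856, estimated 0.951). Cytoplasmic ribosomal proteins were called up (4.7e-06, estimated 0.992) with a median of 0.07 and a mean of -0.01, which differ in sign, and RpS3 (0.22) as the 1 member that passed either way. JNK genes were called down (0.0171, estimated 0.717) with Gadd45 at -0.69 as 1 of 9, and 1 up and 1 down over the list alone. Line marker genes were called up (0.0408, estimated 0.491) through y (3.48), 1 of 3 and 2 over the list alone, but not with a replicate block (0.0517) or without bodies that hold gonad RNA (0.0746). The accessory gland list was called down (0.0178, estimated 0.992), with 0 of 23 called by edgeR, 0 at an unadjusted p under 0.05 and 1 by DESeq2. Beyond the 0 h difference midgut enzymes were still called down (7.2e-05), while the accessory gland list was called up (0.0109), as were apoptosis and DNA damage genes (0.0181), and testis genes down (2.5e-04). Accessory gland (0.0622) and testis genes (0.590) were not called there without bodies that hold gonad RNA. Detoxification (0.179), JNK (0.881), ribosomal protein (0.412), hemocyte (0.734) and line marker genes (0.594) were not called there.

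DNifm differed from shams in 3829 genes at 48 h, 2284 higher and 1545 lower, 600 by 2-fold or more. Cyp4p2 was at 67.4 ± 13.99 against 5.58 ± 5.72 CPM (5.50, SE 0.26, adjusted p = 1.9e-37), and the glutathione transferase gene GstD5 (3R 12375733 to 12376572) at 59.8 ± 33.2 against 2.71 ± 1.42 (4.50, SE 0.29). CG15784 (X 5429571 to 5432526) rose to 3221 ± 1731 from 150 ± 61.6 CPM (4.43, SE 0.21), CG8620 (3L 7158099 to 7158874) to 110 ± 30.9 from 9.51 ± 3.80 and CG13325 (2R 13110769 to 13126014) to 97.1 ± 43.9 from 8.89 ± 5.04. LysS and LysD rose by 3.75 and 3.43, values that rest on the sham, as they were 0.85 and 0.86 with w alone as control and 6.64 and 6.01 with lacZ alone. Cyp4p2, near 0 in w, had 8.33 with w alone and 2.68 with lacZ alone. The kinase gene Nek2 rose by 3.37. CG9825 (2R 22837361 to 22839291) was at 0.979 ± 1.39 against 12.2 ± 9.73 CPM (-4.31), CG10912 (2R 18056064 to 18057065) at 11.4 ± 5.05 against 159 ± 133 (-3.65), CG11912 at 7.42 ± 6.49 against 50.4 ± 33.3 (-2.87) and CG4734 at 19.8 ± 4.94 against 150 ± 38.4 (-2.86). Ugt36Ba (-2.92), pcl (-2.66), CR33013, CG7742, CG31041 and CG43055 were the other named decreases. The count was 1204 without replicate 3, which takes out the female pool with 46.3% ovary RNA, and 1704 without all bodies that hold gonad RNA.

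Ribosomal protein genes rose in 58 of 86 in DNifm, and 68 rose and 1 fell over the list alone, with a median of 0.20 (adjusted p = 1.5e-23, estimated 0.545); RpLP2 had 0.45 and RpL8 0.32. Proteasome genes rose in 30 of 31, and in all 31 over the list alone (1.5e-23, estimated 0.16), with Prosalpha4 at 0.53 and Rpn1 at 0.52. These counts were 57 and 27 without the bodies that hold gonad RNA. Elongation genes rose in 14 of 23, 19 over the list alone (8.3e-07, estimated 0.636), with Larp7 at 0.72 and Set2 at 0.49 next to the expressed Cdk9 itself. Without the bodies that hold gonad RNA 3 rose and 1 fell, and the list was not called (adjusted p = 0.135). Midgut enzymes rose in 9 and fell in 15, 11 and 15 over the list alone (not called at 48 h, adjusted p = 0.1003). They were called down beyond the 0 h difference (4.4e-10, and 2.0e-05 without bodies that hold gonad RNA), both at the preset correlation, as their mean went from 0.30 at 0 h to -0.34 (SE 0.16) at 48 h. The 12 midgut genes that are no digestive enzymes moved with them, from 0.10 to -0.39 (SE 0.09). The 9 enzymes that rose at 48 h were compared with shams, and the enzyme mean was already above shams at 0 h. Their number therefore does not decide whether less midgut tissue accounts for the fall. The 48 h means of both sets include the female pool with 46.3% of the ovary level. At 48 h 10 enzymes rose and 11 fell without bodies that hold gonad RNA, and the list was not called (0.937). Ribosomal (1.1e-10), proteasome (4.3e-15), elongation (1.2e-06), heat shock (0.00412) and accessory gland genes (0.00188) were called up beyond 0 h. Of these only elongation was not called without such bodies (0.219).

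DNifmDNcff differed from shams in 1115 genes at 48 h, 492 higher and 623 lower, 194 by 2-fold or more. GstD5 was at 109 ± 76.9 CPM (5.53, SE 0.28, adjusted p = 1.2e-34), Cyp4p2 at 62.5 ± 9.25 (5.42) and CG15784 at 3053 ± 1581 (4.32). CG9672 (X 16705971 to 16706874) rose to 486 ± 187 from 47.2 ± 10.4 CPM (3.46). LysC, CG8620, LysS and CG13325 rose by 3.65, 3.37, 3.25 and 3.12, but with w alone as control LysC had 0.90 and LysS 0.35 (adjusted p = 0.458), against 6.40 and 6.15 with lacZ alone. Cyp4p2 had 8.24 with w alone and 2.59 with lacZ alone. The eye colour gene w (X 2790599 to 2796466), which marks many transgenes, rose to 174 ± 99.9 from 33.2 ± 40.3 CPM (3.17). The protease gene Jon66Ci (3L 8391540 to 8392377) was at 0.843 ± 1.11 against 41.8 ± 34.4 CPM (-4.88, SE 0.53), CG3085 had -3.89, Porin2 -2.98, Ugt36Ba -1.76 and CG2065 (2R 7663786 to 7665269) -1.74 (19.9 ± 12.4 against 72.8 ± 47.9 CPM). CG31773, Adgf-A2, CR33013, CG6018 and CG32750 were the other named decreases. The count was 446 without replicate 2 and 550 without replicate 3.

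Ribosomal protein genes rose in 36 of 86 in DNifmDNcff, and 63 rose and 1 fell over the list alone (7.3e-33, estimated 0.23), and proteasome genes in 11 of 31, 22 over the list alone (4.0e-15, estimated 0.23). Fat body genes were called up (0.0104, estimated 0.824) with Desat1 at 0.50 and the acetyl-CoA carboxylase gene ACC at 0.38, 4 of 20 either way. Muscle genes were called up (0.00427, estimated 0.824), 2 of 25 and 3 over the list alone. Elongation genes were also called up (0.0451, estimated 0.824), with 3 of 23 either way, but this list holds the expressed Cdk9 itself next to gpp (0.49) and Spt6 (0.16). Its median was 0.03 and its mean 0.22. Line marker genes were called up through w (0.00875, estimated 0.0997), 1 of 3. Ribosomal (5.6e-43), proteasome (1.2e-15) and fat body genes (0.0137) were called beyond the 0 h difference too, unlike muscle (0.723), elongation (0.0555, and 0.0388 without bodies that hold gonad RNA) and line marker genes (0.0722). Beyond 0 h at the preset correlation, but not at 48 h with all bodies, accessory gland (5.4e-09), hemocyte (9.8e-04), heat shock (0.00623), photoreceptor (0.0128), female germline (0.0150) and yolk protein genes (0.0356) were called up and testis genes down (5.7e-04).

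Between the 2 Cdk9 lines 1384 genes differed at 48 h, 480 of them higher in DNifmDNcff. CG14499, CG43055 and CG10912 were higher there by 3.22, 3.14 and 2.23, and the importin gene Pen was lower by a change of -3.18 (14.02 ± 13.9 against 145 ± 292 CPM, n = 6 each), with sip2 at -3.41 and CG46059 at -5.19. Pen is among the genes enriched in gonads, and the difference moved with the DNifm pool that holds ovary RNA. The count was 140 without replicate 3, 135 without bodies that hold gonad RNA and 2 when only these 12 libraries were fitted.

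The stil line differed from shams in 3445 genes at 48 h, 1406 higher and 2039 lower, 701 by 2-fold or more. It differed in 735 genes before the shift, and 2308 changed beyond the 0 h difference. The stress gene TotC (3R 20872988 to 20873580) rose to 314 ± 246 from 10.3 ± 5.37 CPM (4.84, SE 0.51). The antimicrobial peptide genes Dro (2R 14745961 to 14746714), Dpt (2R 18865765 to 18866260) and AttC (2R 13393705 to 13394667) rose by 5.31 (SE 1.02; 3.28 with lacZ alone as control and 7.35 with w alone), 4.11 (SE 0.69) and 3.94, Dpt to 53.8 ± 54.2 from 4.01 ± 8.88 CPM. GstD5 rose to 92.6 ± 13.1 CPM (5.03) and GstD2 (3R 12371971 to 12372704) to 36.9 ± 10.8 from 2.47 ± 1.70 (3.82). CR44145 and CG4500 rose by 4.48 and 4.45. CG4830 (3R 12208159 to 12210360) had -5.68 (SE 0.52), and the protease gene Jon65Aii (3L 6052321 to 6053215) was at 1.96 ± 1.27 against 98.9 ± 70.8 CPM (-5.48). CG15155 (2L 18154851 to 18155942) had -5.25, CG17752 (3R 19610225 to 19612437) -5.09 and CG17751 -4.94. The phosphate transporter gene NaPi-T (2R 14842720 to 14845874) was at 4.05 ± 1.43 against 63.8 ± 10.7 CPM (-4.15). CG10725 and CG7017 were the other named increases, and CG9259, CG16727, CG11892 and CG42833 the other decreases. The count was 2258 without replicate 1.

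Of 27 antimicrobial and immune-induced genes in the stil line 21 rose and 1 fell, 22 and 1 over the list alone (8.7e-08, estimated 0.289), and all 5 Turandot genes rose (2.0e-06, estimated 0.137), TotA by 3.37. Without bodies that hold gonad RNA 8 immune genes rose and 1 fell, with 1 stil male pool left. Midgut enzymes fell in 26 of 38 and rose in 8 either way (3.9e-10, estimated 0.332), with Jon99Fi at -3.19 and thetaTry at -3.08. Detoxification genes rose in 11 of 25 and fell in 8, 12 and 8 over the list alone (4.6e-04, estimated 0.418), with GstD4 at 4.22. The apoptosis and DNA damage list rose in 7 of 16 and fell in 1, 8 and 1 over the list alone (7.4e-04, estimated 0.221), through the end joining genes Irbp (1.59) and Ku80 and the break repair genes rad50 (1.45) and mre11 (0.82). Hemocyte genes rose in 7 of 10, 8 over the list alone (7.2e-05, estimated 0.32), with Hml at 1.40 and NimC1 at 1.02. In the JNK list upd3 (2.04), Gadd45 (1.61) and Ets21C (1.10) rose and kay fell by 0.40 (0.0336, estimated 0.418), with 3 up and 2 down over the list alone.

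Other lists fell in the stil line. Muscle genes fell in 15 of 25 and rose in 1 either way (3.7e-05, estimated 0.519), with Unc-89 at -0.998 and sls at -0.82. Photoreceptor genes fell in 12 of 18, 15 over the list alone (6.3e-04, estimated 0.505), with chp at -0.54 and Rh4 at -0.53. Mitochondrial ribosomal proteins fell in 15 of 72, 11 over the list alone (0.00348, estimated 0.437). Clock genes fell in 5 of 9 either way (0.00794, estimated 0.289), with Pdp1 at -0.72 and tim at -0.56. Immediate early genes fell in 5 of 9, 6 over the list alone (0.00794, estimated 0.357), with jim at -0.74 and CrebA at -0.67. Accessory gland genes were called down (6.9e-08, estimated 0.332) on a median of -1.21, with Acp76A (-1.15) and Obp56g (-0.85) as 2 of 23, 1 over the list alone. Here too low counts in females can make up part of the median. Line marker genes were called up (0.0104, estimated 0.137) with y at 2.39 and w at 2.35, 2 of 3. Without bodies that hold gonad RNA they (0.0755) and the JNK list (0.178) were not called. Of the 14 lists called in this line, accessory gland (0.268), photoreceptor (0.554) and clock genes (0.0629) were not called beyond the 0 h difference, and JNK (0.209) and line marker genes (0.0749) were not called there without bodies that hold gonad RNA. Heat shock genes were called up beyond 0 h (0.00553) but not at 48 h.

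The remaining 8 lists were not called in any line at 48 h with all bodies at the preset correlation. Chorion genes had their lowest adjusted p in DNifm (0.0875), where Cp18 had 3.31. The lowest values were 0.0652 for female germline and 0.0548 for testis genes in DNifmDNcff, 0.0793 for yolk proteins in gpp, 0.0532 for neurons and 0.0876 for Hox genes in DNifm, 0.0509 for ecdysone genes in stil and 0.704 for dosage compensation and sex determination in DNifmDNcff. Within these lists dsx (-0.77) and fru fell and Sxl (0.24) rose in the stil line, where the Hox genes lab (-1.03) and Scr (-0.86) and the hormone response genes Eip71CD (-1.25) and br (-0.51) also fell. With a replicate block neurons were called down in DNifm (0.0432) and DNifmDNcff (0.0497), as were testis genes in DNifmDNcff (0.0495), where hemocyte genes were called up (0.0495). Without bodies that hold gonad RNA testis genes were called up in gpp (1.9e-04) and DNifm (0.00632), although 0 and 1 of 26 rose and their medians with all bodies were -0.05 and -0.62. Female germline genes were then called up in DNifmDNcff (0.00137), with 1 of 18 rising, and neurons there down (0.00135), with 2 of 13 falling. Of the other lists, muscle (0.00632, with 4 of 25 rising) and photoreceptor genes (0.00266, with 6 of 18 rising) were then called up in DNifm, and muscle in SuTpl (0.00175) and Turandot genes in gpp (0.0375) down. These calls were made at the preset correlation only.

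**Figure D3:**
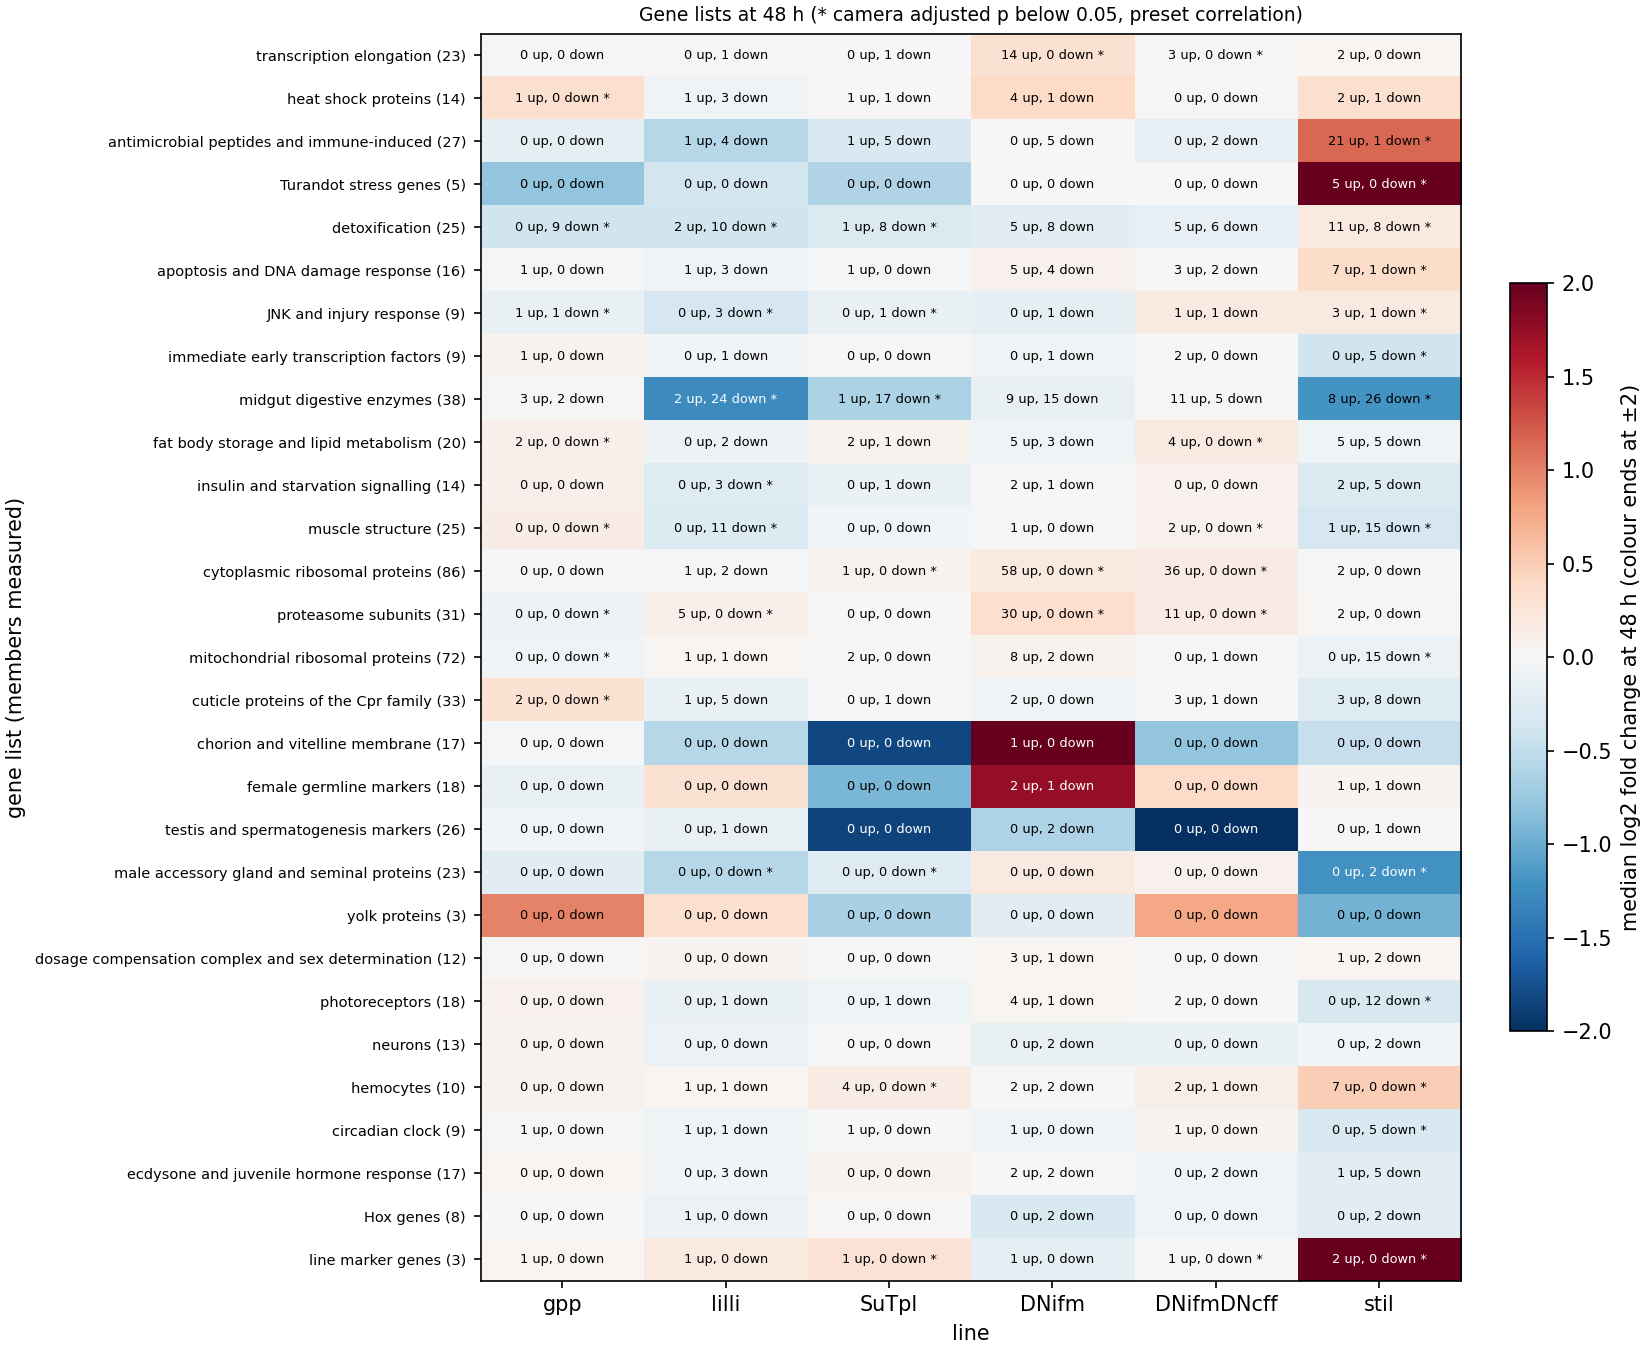
Median log2 fold change of each gene list (rows, members measured in brackets) in each line at 48 h (columns) as colour, with the number of members that passed in each direction and a star for a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation no list kept its star, and the midgut enzymes had medians of -1.27 in lilli and -1.20 in stil.

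At 24 h the counts were 1265 in gpp, 1167 in lilli, 1229 in SuTpl, 1045 in DNifm, 682 in DNifmDNcff and 3096 in stil. CG11313 (3R 30729837 to 30731165) was higher by 7.03, 7.11 and 7.23 in the 3 RNAi lines. In the lilli line Hsp70Bb rose to 26.4 ± 5.48 from 2.25 ± 1.88 CPM (n = 6 and 12), and the cytokine gene upd3 had -5.44. Jon66Ci had -6.52 in DNifm, where w was at 235 ± 62.2 against 32.02 ± 26.5 CPM. In the stil line Dpt rose to 65.7 ± 66.9 from 0.707 ± 0.978 CPM, Fbp1 by 6.03, and CG4830 and Jon65Aii had -6.92 and -5.53. mthl8 (3L 22428 to 26308), a receptor gene, was at 12.4 ± 8.58 CPM in shams and 0 in every library of lilli, SuTpl and both Cdk9 lines. Midgut enzymes fell in 16 of 38 in lilli (20 over the list alone), 21 in SuTpl (22), 15 in DNifm (18), 9 in DNifmDNcff (10) and 26 in stil, while 10 rose in gpp (12), and proteasome genes rose in 26 of 31 in stil (29). Ribosomal protein genes rose in 48 of 86 in gpp, but only 1 rose without replicate 2 of every group, and 1 of 84 with only the contrast's libraries fitted. Their median log2 change was 0.18 in the full fit, 0.08 without replicate 2 and 0.19 with only the contrast's libraries. In the last setting calls were thus lost without a smaller shift. Midgut enzymes that rose in gpp numbered 4 without replicate 2. Replicate 2 of gpp females at 24 h stood apart, with the fewest genes detected of all bodies (10828) and the highest share of counts in 10 genes (19.96%). The gpp count was 341 with only the contrast's libraries fitted and 325 without replicate 2. Without replicate 1 the counts were 653 in lilli, 525 in SuTpl, 486 in DNifm and 216 in DNifmDNcff, and without replicate 2 the stil count was 1852.

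At 0 h, before the shift, the counts were 2093 in gpp, 1055 in lilli, 821 in SuTpl, 470 in DNifm, 619 in DNifmDNcff and 735 in stil. CG11313 was at 28.3 ± 11.5, 32.8 ± 12.4 and 34.5 ± 9.65 CPM in the RNAi lines (n = 8 each) against 0.206 ± 0.310 in shams (n = 15). lectin-24A (2L 3716800 to 3717773) was higher in gpp, lilli and SuTpl by 4.195, 4.52 and 4.47 (1.57, 1.89 and 1.85 with lacZ alone as control), and CG33509 (2L 21084605 to 21086506) by 4.22, 3.91 and 3.39. mthl8 was at 8.98 ± 3.41 CPM in shams, at 0.0637 ± 0.119 in gpp and at 0 in every lilli, SuTpl and DNifmDNcff library. CG32368 (3L 7915437 to 7915846) had -3.25, -3.31 and -3.17 in the RNAi lines. CG11893 (3R 25289889 to 25291366) rose to 18.4 ± 6.85 and 24.5 ± 8.44 CPM in the Cdk9 lines from 0.689 ± 0.788. In the stil line the chorion genes Cp16, Cp19 and Cp18 were higher by 4.57, 3.83 and 3.53, and they moved with replicate 1, whose female and male pools had 6.98% and 4.50% of the ovary marker level and were always left out together. CG44142, at 0 CPM in w, changed sign in 5 named contrasts with lacZ alone as control. Without replicate 2 the counts were 617 in gpp, 484 in lilli, 319 in SuTpl and 328 in DNifmDNcff, without replicate 4 the DNifm count was 263, and without replicate 1 those of gpp and stil were 683 and 359.

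**Figure D4:**
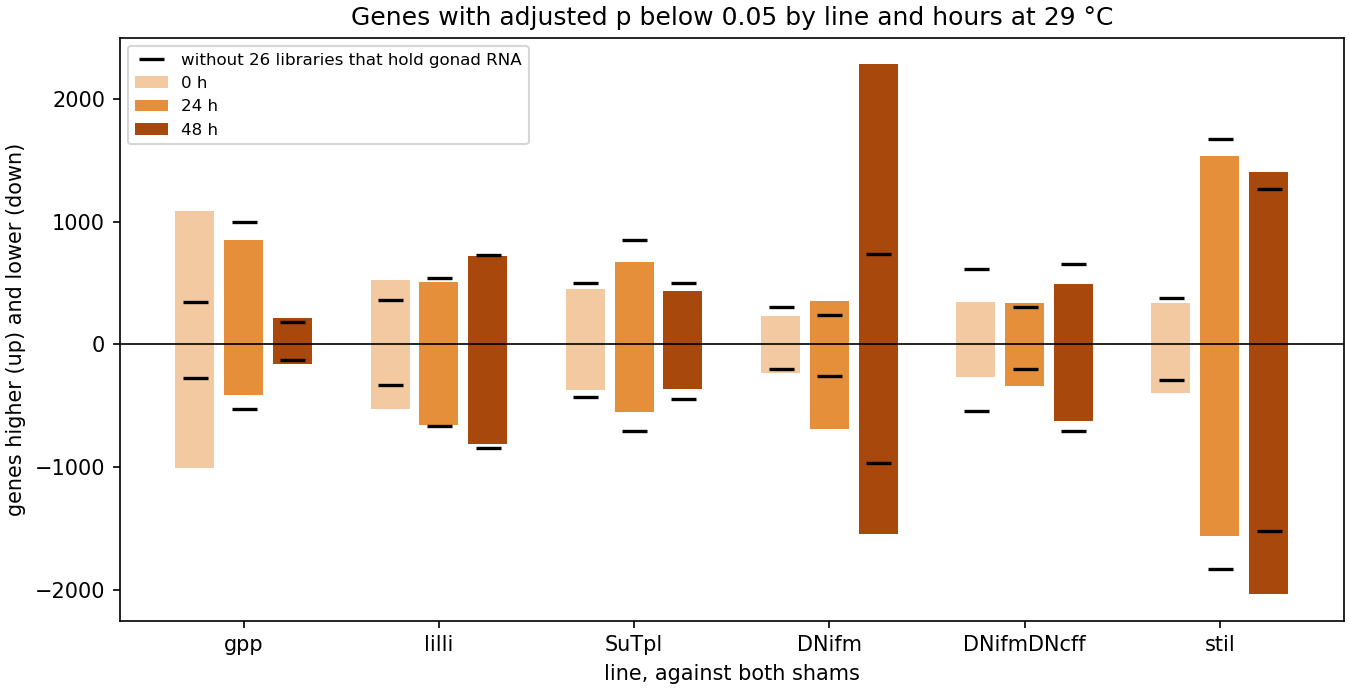
Number of genes higher (upward) and lower (downward) in each line than in shams at 0, 24 and 48 h, with dashes for the numbers without the 26 bodies that hold gonad RNA. At 48 h the stil line had 1406 higher and 2039 lower genes, and gpp 211 and 163.

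Beyond the 0 h difference, 492 genes changed by 48 h in gpp, 393 in lilli, 99 in SuTpl, 1594 in DNifm, 424 in DNifmDNcff and 2308 in stil. In gpp CG12766 and CG17636 rose by 1.63 and 1.32 and Fcp3C, a follicle cell gene, had -3.16. Of these only CG12766 stayed called without bodies that hold gonad RNA, among them the 2 gpp female pools at 0 h with 29.0% and 17.7% of the ovary level. The counts were then 35 in gpp and 670 in DNifm. In lilli PH4alphaPV rose by 2.83 and Cyp4p2 by 3.51, while CG10513, Lsp2 and CG8299 had -3.08, -3.06 and -2.76, and 17 of 38 midgut enzymes fell (23 over the list alone). In SuTpl Porin2 had -3.03 and MtnB -2.45, and CG12766 rose by 1.27. In DNifm and DNifmDNcff GstD5 rose by 4.69 and 5.13 and the chitinase gene Cht9 (2R 21067992 to 21069286) by 3.78 and 3.61. Ribosomal protein genes rose in 17 and 30 of 86 in these lines and proteasome genes in 19 and 3 of 31. In stil CG4500 and Dro rose by 6.24 and 5.74, and CG4830, CG17752 and CG15155 had -6.40, -5.50 and -5.44. The count was 56 in gpp and 211 in lilli without replicate 1, 126 in gpp, 18 in SuTpl and 123 in DNifmDNcff without replicate 2, and 466 in DNifm without replicate 3.

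The response at 48 h differed between the sexes in 9 genes in gpp, 22 in lilli, 8 in SuTpl, 1683 in DNifm, 5 in DNifmDNcff and 163 in stil. CR40469 (X 122493 to 122706) had male minus female values of -3.42 in gpp and -3.70 in SuTpl, with 2.91 in females and -0.34 in males of lilli. CG9360 (X 11763474 to 11764590) had -1.90, -1.52 and -1.62 in gpp, lilli and SuTpl, and the demethylase gene Su(var)3-3 (3L 20226381 to 20230250) -1.34 in lilli and -1.50 in SuTpl. Gnmt had 3.36 in lilli and 3.10 in SuTpl. In DNifm Cp18 (3L 8726791 to 8727613), bora and Chd3 had -6.15, -6.18 and -6.27, with Cp18 at 82.3 ± 199 CPM over the 6 DNifm pools, and these moved with the pool that holds ovary RNA. In DNifmDNcff w (2.02, but 4.04 with lacZ alone as control and -0.003 with w alone), CG34215 (-1.82), mRNA-cap (-0.57), Cyp4d21 and fs(1)K10 passed. In stil CG31091 and Obp99b had -5.00 and -4.62, and CG9825 3.73. Without replicate 3 the DNifm count was 7. Without replicate 2 the counts were 2 in gpp, 1 in lilli, 1 in SuTpl and 2 in DNifmDNcff, and without replicate 1 the stil count was 45. The Wald test of DESeq2 called many more such genes in gpp, lilli, SuTpl, DNifmDNcff and stil, with counts given below.

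Some lines shared changed genes at 48 h, but all used the same 12 sham pools, which alone gives correlation. Calls at 48 h also hold differences present before the shift. The RNAi lines shared some of these at 0 h, such as CG11313, and separate shams do not remove them. SuTpl had 797 calls at 48 h but 99 beyond 0 h, and lilli 1534 and 393. As the contrast beyond 0 h also has a larger SE, these counts do not measure the share present before the shift. Unchanged simulated groups shared 0 called genes in every pair, and independent lists leave out the shared shams, so an excess over either is not in itself a shared effect. lilli and SuTpl had a correlation of log2 fold changes of 0.599 over 12468 genes, against 0.328 simulated with no change, and a covariance of 0.0775 against 0.0217. With separate controls the correlation was 0.355, against -0.016 simulated. Both rose in 292 genes and both fell in 297, against 24.8 and 24.0 for independent lists, with 4 opposite. With a different sham for each line these were 138.5 and 200.5, against 14.1 and 19.98, with 18 opposite. DNifm and DNifmDNcff had 0.555 against 0.343 simulated, a covariance of 0.103 against 0.0236 and 0.383 with separate controls. They shared 342 higher genes, against 90.1 for independent lists, and 501 lower, against 77.2, and 185 and 307.5 with separate shams, against 52.6 and 51.5. Without bodies that hold gonad RNA, among them the DNifm female pool with 46.3% of the ovary level, they shared 378 and 466, against 39.98 and 56.5. SuTpl and DNifmDNcff had 0.444 against 0.318 simulated, a covariance of 0.0652 against 0.0216 and 0.247 with separate controls, with 84 genes higher in both, 81 lower and 73 opposite, against 17.01, 18.3 and 35.98 for independent lists, so opposite genes were in excess as well. With separate shams opposite genes were the largest class, with 31, 53.5 and 78.5, against 9.29, 13.5 and 22.6. gpp and lilli had 0.317 against 0.320 simulated, but a covariance of 0.036 against 0.0216 and 0.0926 with separate controls, against -0.0171. They shared 89 higher genes, against 12.1 for independent lists, and 82 lower, against 10.7, with 23 opposite, and 41.5, 45.5 and 37 with separate shams.

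DNifm and stil, lilli and DNifm, and lilli and stil had correlations of 0.192, 0.252 and 0.191, below the simulated 0.323, 0.326 and 0.356, but covariances of 0.0511, 0.0414 and 0.0411, against 0.0218, 0.0218 and 0.0236, and 0.101, 0.0976 and 0.0763 with separate controls. Genes lower in both DNifm and stil numbered 605, against 253 for independent lists, and opposite ones 376, against 548, but without bodies that hold gonad RNA 252 were opposite, against 193.5. With separate shams these were 441, against 186, and 317, against 367. lilli and stil had 122 genes higher in both, 354 lower and 334 opposite, against 80.9, 134 and 209, and with separate shams 52, 280 and 310.5, against 50.5, 107 and 149, so no excess of genes higher in both was left. Negative correlations were seen in 3 pairs. gpp and DNifmDNcff had -0.0943 against 0.317 simulated (-0.232 with separate controls), although 66 genes were higher in both and 54 lower, against 8.33 and 8.14, with 18 opposite, against 16.98. With separate shams these were 19.5, 29.5 and 33. SuTpl and stil had -0.175 against 0.336 (-0.252), with 65 genes higher in both, 140 lower and 234 opposite, against 48.6, 59.9 and 112, and 29, 108 and 206.5 with separate shams, against 27.8, 48.5 and 75.3. DNifmDNcff and stil had -0.170 against 0.336 (-0.238), with 105, 236 and 182, against 55.5, 102 and 151, and 55, 149 and 177.5 with separate shams, against 33.2, 71.6 and 98.1.

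No X to autosome difference from shams passed in any line or sex at 48 h by the exact permutation test over all genes, with an adjusted p of 0.893 throughout. A single difference could not pass after adjustment with so few pools. The largest differences were 0.0668 in SuTpl males (0.155 ± 0.0187, n = 3, against 0.0878 ± 0.0552, n = 6; exact p = 0.0833) and 0.0675 in stil males (0.155 ± 0.0557; exact p = 0.155). Sham females had 0.345 ± 0.0362. With gonad-enriched genes left out, an alternative chosen after seeing the data, differences passed in stil females (0.0303) and in males of SuTpl (0.0444), DNifmDNcff (-0.0391) and stil (0.136), each at an adjusted p of 0.0357. The result thus depended on the genes averaged, and the values over all genes went with gonad RNA. Sham males with 4.22% and 4.64% of the testis level had 0.0297 and 0.00562, and the other sham males 0.115 to 0.132. In stil males, pools with 5.63% and 4.98% had 0.130 and 0.117, and the other pool 0.219. The DNifm female pool with 46.3% of the ovary level had 0.548. The sham male mean thus includes pools with testis RNA.

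**Figure D5:**
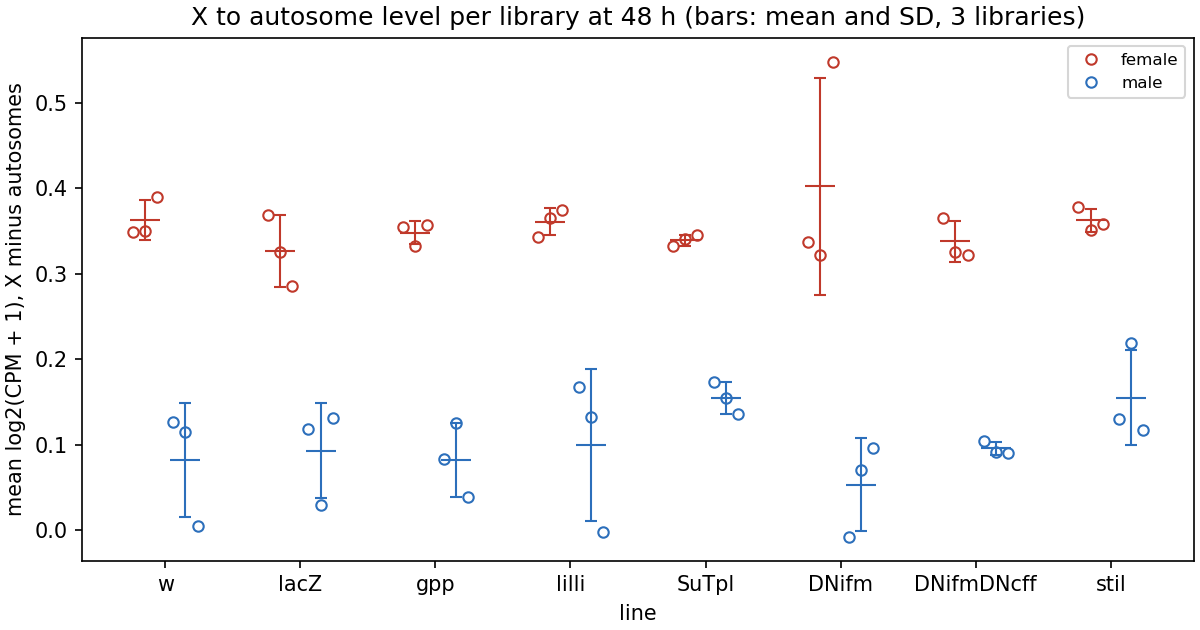
X to autosome value of each 48 h body library (mean log2 of CPM plus 1 over X genes minus autosomal genes) by line and sex, with bars for the mean and SD of 3 pools. Sham males averaged 0.0878 and sham females 0.345, and over all genes no line passed the test against its shams, though 4 of 12 differences passed with gonad-enriched genes left out.

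In gonads at 0 h the 3 RNAi lines were compared with the same 4 lacZ pools per organ, so a level particular to lacZ gives the same difference in all of them. In ovaries Syt4 (3R 7266065 to 7270809), a synaptotagmin gene, was at 9.36 ± 2.62, 7.11 ± 1.41 and 7.41 ± 1.58 CPM in gpp, lilli and SuTpl against 0.220 ± 0.164 in lacZ (n = 4 each). CR40469 was at 43.6 ± 5.88, 32.3 ± 6.56 and 40.6 ± 5.93 against 2.73 ± 0.761 CPM. CG2993 (3R 7804665 to 7810014) had -2.18, -2.29 and -2.66, and CG14715 (3R 11674221 to 11674923) was higher by 2.50 in lilli and 2.76 in SuTpl. In testes CR44017 (3R 6408978 to 6409578), which lies within the gpp locus, was at 33.9 ± 2.36, 30.2 ± 1.86 and 32.9 ± 3.22 CPM against 0.173 ± 0.347, and CG5873 (3R 17425768 to 17446499) was higher by 5.64, 5.63 and 5.23. CR43422 (2R 22291717 to 22292395) was higher by 5.00 in gpp and 5.23 in lilli. CR42836 (3R 20139148 to 20139921) was at 20.4 ± 5.54 CPM in lacZ testes and 0 in gpp. The Y gene Pp1-Y1 (Y 9833 to 10786) was at 0 CPM in SuTpl testes against 10.9 ± 1.36 in lacZ.

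The testis counts were 622 in gpp (377 higher), 809 in lilli (460 higher) and 759 in SuTpl (431 higher), with 366 without replicate 1, 465 without replicate 2 and 442 without replicate 3 in turn. The ovary counts were 280 in gpp (150 higher) and 164 in lilli (76 higher). Without replicates 1, 2 and 4 in turn the gpp ovary count was 129, 144 and 144, and without replicate 4 the lilli ovary count was 80. SuTpl ovaries had 1581 changed genes, 1481 higher and 100 lower, on a median shift of 0.17 over all genes. CG18446 was at 177 ± 4.80 against 49.4 ± 3.59 CPM, 2.04 higher, and the antifungal gene Drs and CR43767 had -4.61 and -2.96, all beyond that shift. With RLE scaling 116 were higher and 110 lower, and with ovaries fitted alone 198 and 172. The SuTpl ovary count was 884, 140 and 343 without replicates 1, 2 and 4. Of 19 midgut enzymes measured 4 were higher in gpp ovaries (16 over the list alone).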

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

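The tests of the enzyme lists at 0 h, the counts of enzymes that rose, and the scaling of ovaries alone were chosen only after the results they measure were seen, and the alternative without bodies that hold gonad RNA was added after seeing the data.

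DNifm changed 1683 genes differently in the sexes at 48 h, with 1373 of them lower in males relative to females, with Chd3, bora and the chorion gene Cp18 among the largest. Ovary RNA in DNifm females is a candidate explanation, since 10 sex-different genes were left without the bodies that hold gonad RNA. A response to dominant negative Cdk9 that differs between the sexes was argued against as the source of this count, since 7 genes were left without replicate 3 of every group. Ovary RNA as the whole of the DNifm change at 48 h was excluded, since 1704 genes still changed without the bodies that hold gonad RNA, against a median of 1367 in the other 5 lines. Removing a pool also lowers the power of the test, and smaller sex differences stay open.

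Midgut digestive enzymes were lower in lilli, SuTpl and stil at 48 h, with mean changes of -0.88 (SE 0.08), -0.47 (SE 0.08) and -0.96 (SE 0.15) over 38 genes. Less midgut tissue in the stil bodies may contribute, as 12 midgut genes that are no digestive enzymes had a mean of -0.78 (SE 0.09). The 8 enzymes that rose in stil were compared with shams, and its enzyme mean was already above shams at 0 h. Their number therefore does not decide whether less midgut tissue is the whole change there. The same 12 genes had -0.40 (SE 0.06) in lilli and -0.16 (SE 0.06) in SuTpl, less than the enzymes, and 2 and 1 enzymes rose. Less midgut would lower both sets alike and lower enzyme expression only the enzymes, and as these values lay in between, the shares of each cannot be told apart in lilli and SuTpl. A line difference of stil present before the shift was excluded, since its enzymes had a mean of 0.25 (SE 0.09) at 0 h, while 0 h means of -0.23 (SE 0.08) in lilli and -0.18 (SE 0.09) in SuTpl leave a smaller one open there.

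SuTpl ovaries had 1481 higher and 100 lower genes than lacZ ovaries. Tissue of the rest of the body was excluded as the source, since 3.38% of the higher genes were at least 5 times higher in lacZ female bodies. With the ovaries scaled alone 53.5% of the calls were higher, but that scaling centres the changes on 0 whether or not a shift is real, so the test decides nothing. The SuTpl ovary libraries were also deeper, and with these thinned to the lacZ depth 172 genes were called, 90 of them higher. Thinning keeps each gene's share of the counts, yet the median change over all genes went from 0.17 to 0. Thinning also moved the scaling factor, from 1.11 to 1.24 against 1.27 in lacZ ovaries. The 0.17 thus went with the scaling factor, and changes centred on 0 in this way do not decide whether many genes rose. Depth and scaling over ovaries and testes together cannot be told apart.

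A gonad marker level far from the other 3 pools was seen 4 times among 33 runs of Dixon's ratio test on groups of 4 pools, some of them on target gene levels, and so many runs pick some pools by chance. Replicate 2 of DNifm females at 0 h had 5.55% of the ovary level, replicate 1 of lilli females at 0 h had 6.21% and replicate 1 of stil females at 0 h had 6.98%. Replicate 4 of DNifmDNcff males at 0 h had 1.89% of the testis level.

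The number of genes that changed differently in the sexes at 48 h differed between lines, with 9 in gpp, 22 in lilli, 8 in SuTpl, 1683 in DNifm, 5 in DNifmDNcff and 163 in stil. The number changed at 48 h beyond 0 h also differed, with 492 in gpp, 393 in lilli, 99 in SuTpl, 1594 in DNifm, 424 in DNifmDNcff and 2308 in stil. The gpp and DNifm numbers fell strongly without bodies that hold gonad RNA, as given below, so the order of the lines rests in part on such bodies.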

How the results depend on the processing

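Leaving out the bodies that hold gonad RNA and leaving out gonad-enriched genes were chosen after seeing the data. Of 46 results, the size factors of DESeq2 kept 45 within 1.5 times of the reported count, as did no filter, and a mean CPM of at least 5 kept 44. All 52 results with a replicate block stayed within that range. No X to autosome difference passed with the median, a minimum of 10 CPM, a pseudocount of 0.1, 24 h libraries or permutations within replicate numbers, but their sizes moved, and with so few pools a single difference could not pass, so this does not show stability. Leaving out a replicate of every group also removes samples, and 29 of 58 results stayed within range without replicate 1, 30 without 2, 40 without 3 and 11 of 19 without 4. Of the 58, 12 were X to autosome differences, which did not pass with all pools and could not pass with fewer. Another 6 were target genes, judged by whether they were called. These shares therefore do not measure the stability of the gene counts alone. Among named genes 448 of 452 stayed called with RLE, 441 of 446 with DESeq2, 432 of 452 with no filter, 427 of 452 with the block, 300 of 352 with lacZ alone, 263 of 352 with w alone, 289 of 374 with only the contrast's libraries, 301 without gonad RNA and 340 of 452 without replicate 3. In the simulation, with the same dispersion for all genes, 53.7% of 1.5-fold changes were recovered, and depth alone was not tested. Where no construction is named below, the cause was not tested.

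With the Wald test of DESeq2, which made more false calls in the simulation, the counts were 607 at 48 h in gpp, 918, 649, 437 and 993 beyond 0 h in gpp, lilli, SuTpl and DNifmDNcff, and 107, 154, 119, 178 and 411 between the sexes in gpp, lilli, SuTpl, DNifmDNcff and stil. They were 410 between sham lines, 512 in gpp ovaries and 332 in SuTpl ovaries.

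With w alone as control, which leaves fewer control pools, the counts were 667 and 792 at 24 h in gpp and SuTpl, 682 and 424 at 0 h in lilli and stil, 899 beyond 0 h in DNifm, and 5, 789, 1 and 93 between the sexes in lilli, DNifm, DNifmDNcff and stil. With lacZ alone they were 1375 at 0 h in gpp, 78, 39 and 140 beyond 0 h in gpp, SuTpl and DNifmDNcff, and 1068 and 87 between the sexes in DNifm and stil. With only the contrast's libraries fitted, which leaves fewer samples for the dispersion, they were 341 at 24 h and 1327 at 0 h in gpp, 956 at 48 h and 573 beyond 0 h in DNifm, 5 and 1 between the sexes in gpp and DNifm, and 2 between the Cdk9 lines, and gpp in its line passed at -0.34.

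Without bodies that hold gonad RNA the counts were 617, 689 and 1152 at 0 h in gpp, lilli and DNifmDNcff, 503 at 24 h and 1704 at 48 h in DNifm, 35 and 670 beyond 0 h in gpp and DNifm, 14, 10 and 38 between the sexes in lilli, DNifm and stil, and 135 between the Cdk9 lines. This setting left a single pool of stil males at 48 h, and of DNifm and DNifmDNcff females and lacZ males at 24 h, so other groups supplied the spread there. gpp in its line passed at -0.35, and 5 lists were called in DNifm. With gonad-enriched genes left out, so that fewer genes were tested, the counts were 726 between the sexes in DNifm, 829 between the Cdk9 lines and 3391 between sham sexes. X to autosome differences then passed at 0.0303 in stil females, 0.0444 in SuTpl males, -0.0391 in DNifmDNcff males and 0.136 in stil males, each with an adjusted p of 0.0357.

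A mean CPM of at least 5, which tests fewer genes, gave 3374 between sham sexes and 920 in SuTpl ovaries. SuTpl ovaries had 226 with RLE, 213 with no filter and 370 fitted alone, when gpp and lilli ovaries had 695 and 248. With an estimated correlation 0 lists were called by camera in gpp, lilli, SuTpl, DNifm, DNifmDNcff and stil. In the contrast of 48 h beyond 0 h, 4, 6 and 10 lists were called in SuTpl, DNifm and DNifmDNcff. Without bodies that hold gonad RNA, chosen after seeing the data, it called 12, 4, 7 and 15 in lilli, SuTpl, DNifm and DNifmDNcff.

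Leaving out each replicate number in turn gave, at 48 h, 150 to 293 in gpp, 921 to 1148 in lilli, 372 to 495 in SuTpl, 1204 to 3873 in DNifm, 446 to 784 in DNifmDNcff and 2258 to 2917 in stil. At 24 h it gave 325 to 1198 in gpp, 653 to 717 in lilli, 525 to 862 in SuTpl, 486 to 835 in DNifm, 216 to 579 in DNifmDNcff and 1852 to 2932 in stil. At 0 h it gave 617 to 2800 in gpp, 484 to 987 in lilli, 319 to 662 in SuTpl, 263 to 333 in DNifm, 328 to 548 in DNifmDNcff and 359 to 574 in stil. Beyond 0 h it gave 56 to 681 in gpp, 211 to 302 in lilli, 18 to 78 in SuTpl, 466 to 2033 in DNifm and 123 to 286 in DNifmDNcff. Between the sexes it gave 2 to 8 in gpp, 1 to 14 in lilli, 1 to 5 in SuTpl, 7 to 2451 in DNifm, 2 to 5 in DNifmDNcff and 45 to 82 in stil. It gave 140 to 1507 between the Cdk9 lines, 2861 to 3992 between sham sexes and 88 to 144 between sham lines. Ovaries had 129 to 197 in gpp, 80 to 98 in lilli and 140 to 1409 in SuTpl, and testes 366 to 472, 465 to 614 and 442 to 604. The gpp target had -0.416 to -0.262.

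Some named genes reversed. CG44142 had -0.10, -1.37 and -0.29 at 24 h in gpp, lilli and DNifmDNcff and -0.035 and -0.005 at 0 h in SuTpl and DNifmDNcff with lacZ alone. CG42705 between the sexes in lilli had -0.19 to 7.86 over the replicates left out, lowest without replicate 3, and -0.16 without gonad RNA. CG13114 at 0 h in DNifm had -0.33 without replicate 2 and up to 4.30 without replicate 3. Between the sexes in DNifm bora had 1.31 without gonad RNA, and Cp18 had 0.72 then and -7.21 to 0.64 over the replicates left out, highest without replicate 3. The w gene between the sexes in DNifmDNcff had -0.003 with w alone as control. Cp18 at 0 h in stil had -0.64 without gonad RNA and -0.61 to 4.09 over the replicates left out, lowest without replicate 1. CG42704 in SuTpl ovaries had -2.79 to 0.016 over the replicates left out, highest without replicate 3.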

Other observations

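The splits below were drawn from the libraries of each comparison with both shams pooled, so the real counts differ from those of the full fit. At 48 h the real split exceeded all others in every line, and chance can be excluded: gpp had 216 genes against at most 1 in another split, lilli 1722 against 635, SuTpl 925 against 2, DNifm 1102 against 7, DNifmDNcff 1249 against 11 and stil 3814 against 0. At 24 h chance can also be excluded, with 260 against 113 in gpp, 1214 against 149 in lilli, 1194 against 1 in SuTpl, 961 against 71 in DNifm, 651 against 39 in DNifmDNcff and 3303 against 190 in stil. The same held at 0 h, with 1210 against 403 in gpp, 911 against 136 in lilli, 716 against 59 in SuTpl, 303 against 0 in DNifm, 678 against 17 in DNifmDNcff and 599 against 41 in stil. In gpp, female replicates 1 and 2 at 0 h had 17.7% and 29.0% of the ovary level, and both lie in the real split. Such splits cannot exclude ovary RNA as a source of the gpp count at 0 h.

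Beyond 0 h chance can be excluded with 294 against 57 in gpp, 406 against 0 in lilli, 461 against 18 in DNifmDNcff and 2460 against 1391 in stil. The gpp value carries the same limit as at 0 h, since the gpp pools with ovary RNA are in this contrast. In SuTpl (103 against 287) and DNifm (557 against 834) 2 of 60 splits were as large, the real one included. That share was not adjusted over the comparisons and another split lay above the real one, so chance could not be excluded there. For the response that differs between the sexes 2 of 60 splits were as large in gpp (3 against 262), lilli (10 against 736), SuTpl (5 against 109) and stil (199 against 615). For the same reasons chance could not be excluded in these lines. Splits that called many more genes than the real one point to a structure of the samples whose source was not tested. In DNifmDNcff 7 of 60 splits were as large (1 against 11), so chance could not be excluded there. In DNifm the real split called 0 genes by edgeR, which makes all 60 as large (the highest had 95), so chance could not be excluded for that count and the 1683 genes of the full fit were not tested.

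Between the 2 Cdk9 lines chance can be excluded for the 2 genes of that fit (against 0 in the others), while the 1384 genes of the full fit were not tested. It can be excluded for the sham sexes (3967 against 1), the sham lines (215 against 4) and shams at 0 h and 48 h (5049 against 4). In gonads the real split of 35 exceeded the others in every comparison, with 957 against 1, 262 against 0 and 246 against 29 in gpp, lilli and SuTpl ovaries and 881 against 1, 982 against 1 and 458 against 3 in their testes.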
